A study of Mus musculus with 2 samples.

How the data were processed

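Single-cell RNA was measured in hippocampal cells of 7-week-old mice of 2 genotypes. WT stands for C57BL6/J mice, and 60TM for a line on the same background that carries a human GFAP transgene and serves as a model of Alexander disease. Per the labels, hippocampi were dissociated with papain, and cells were captured with the 10x Genomics Chromium 3' kit, version 3. Each genotype has 1 library pooled from 3 mice, and no map from barcodes to mice was used. The labels give an average of 63967 reads per cell for WT and 54044 for 60TM.

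The deposited matrices hold raw counts of unique molecular identifiers (UMIs) per gene and barcode, with no normalization by the authors. Per the file headers they were made with Cell Ranger 5.0.0, and per the labels reads were aligned to the mouse genome build GRCm38. The deposited gene and barcode tables hold names only and no measured values (unit: other). The lowest barcode total was 500 UMIs in the WT library and 502 in the 60TM library, so the barcodes had been called as cells. Whether intronic reads were counted, and which annotation release was used, is not given in the sources used here. Of 32285 genes, 32235 matched GENCODE M21 on the same build by identifier, from which coordinates and gene types were taken.

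The WT library held 6861 barcodes, 63532407 UMIs and a median of 7053 UMIs and 2644 genes per barcode. The 60TM library held 8733 barcodes, 80684152 UMIs and a median of 7270 UMIs and 2657 genes. Barcodes with fewer than 500 genes (264 in WT and 338 in 60TM) or with over 15% of UMIs from mitochondrial genes (232 and 384) were removed. Doublets were scored per library with Scrublet as run by scanpy, and the barcodes with the highest scores were removed up to an expected rate of 0.8% per 1000 barcodes. This took 377 barcodes (5.49%) in WT and 610 (6.98%) in 60TM. Scrublet's automatic threshold would have taken 228 (3.32%) and 315 (3.61%). The cells kept numbered 6086 in WT (57480919 UMIs) and 7574 in 60TM (70610233 UMIs). No cell sorting is named in the labels.

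Both libraries were clustered together without integration, so that differences between genotypes were not removed. Counts were scaled to 10000 UMIs per cell and log-transformed, genes seen in at least 10 cells were kept, and 2000 variable genes, 30 principal components, 15 nearest neighbours and Leiden clustering at resolution 1 gave 32 clusters. Clusters were named from fixed markers of 21 cell classes (129 genes). A marker counted for a cluster when its log2 ratio to the other clusters was at least 1 and at least 20% of the cluster's cells had a UMI of it, and a class needed 3 such markers. The class with the highest median log2 ratio gave the name. A cluster stayed unnamed when the next class reached over 66.7% of that median, when its median depth was under 33.3% of its libraries' without an own marker among its 10 leading genes, or when its leading genes held more markers of another class. The markers were chosen before the data were examined, but this naming rule was set after the clusters had been seen. Unnamed clusters held 10.7% of WT cells and 17% of 60TM cells and belong to no class.

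Within each class, raw UMIs were summed per library and scaled to the UMI total of the class (CPM). The ratio is 60TM CPM over WT CPM, with an exact conditional-binomial 95% interval. Sums have exact Poisson intervals and shares of cells exact Clopper-Pearson intervals. All intervals cover counting error only. Because each genotype has 1 library, no difference was tested between genotypes, no p-values are given, and no replicate check or paired analysis was possible. Genes with at least 100 UMIs in a class over both libraries were counted as at least 2-fold higher or lower, in classes with at least 50 cells in each library. Where WT or 60TM had 0 UMIs, the fold is a lower bound against a floor of 3 UMIs in that class and library. With 1 to 3 UMIs the ratio of the main setting is given with its counting interval, while most ratios under alternatives are given without. A share of 0 cells is given with the limit that 3 cells would set.

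For 30 gene lists, the median log2 ratio of CPM + 5 was taken over members with at least 20 UMIs in the class, where at least 3 members had them. A member counts as higher or lower at a ratio of 1.5 or more in either direction. Each median has a 95% interval from 1000 Poisson resamples of the counts. Its percentile among 10000 random lists of the same size, matched on expression in 20 bins, serves as a description of these libraries. Shares of cells with a UMI of a gene were computed after thinning each cell to 2000 UMIs, leaving out shallower cells, beside the share without thinning.

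The named genes of each main class (astrocytes, microglia, oligodendrocytes and oligodendrocyte precursor cells, OPCs) follow a rule. Among genes with at least 100 UMIs, they are the 12 with the highest and the 12 with the lowest ratio, ranked by the bound of the interval nearest to 1. Mitochondrial, ribosomal protein, haemoglobin and Y-linked genes and Xist were left out, as were markers of another class and genes with a mean CPM under 1/10 of that in another class. This left 9501 genes to rank in astrocytes, 9135 in microglia, 8818 in oligodendrocytes and 3918 in OPCs. Gfap, Entpd2 in astrocytes, P2ry12 in microglia and the members of each list with the most UMIs or the largest ratios were added. Values of some list members are not reported here. The lists, this rule, the cell filters, the scaling and 48 alternatives were chosen before the data were examined. A further 7 alternatives, 1 further gene list and the genes said to be chosen later were added after the values had been seen. The alternatives covered scaling (including trimmed mean of M-values factors from edgeR), aggregation of cells, cell filters, doublet removal, clustering, UMI minimums, pseudocounts, thinning depth and subtraction of free RNA, and their effect is given in the closing section.

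The calculation was tested on simulated data in which the UMIs of both libraries were drawn from the same profile, with 200 genes per class set to 2-fold or 4-fold. Intervals held the true ratio for 95.4% of genes in astrocytes, 95.4% in microglia, 95.6% in oligodendrocytes and 96.1% in OPCs. All 4-fold genes passed a ratio of 2, against 0, 0, 2 and 1 of the genes left equal in the same classes. The simulation drew Poisson counts without differences between mice, handling or cells. These figures therefore cover counting error only and are not error rates of the gene counts below. Genes set 2-fold higher had median ratios between 1.91 and 1.97, and genes set 2-fold lower between 0.480 and 0.500. Analyses used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2, umap-learn 0.5.12, scikit-learn 1.9.0, scikit-image 0.26.0 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16.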

Results

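The data are UMI counts per gene in single hippocampal cells of 7-week-old mice, from 1 WT library and 1 library of 60TM mice, which carry a human GFAP transgene as a model of Alexander disease, a disorder of astrocytes caused by altered GFAP. Each library pools 3 mice. After filtering, the WT library held 6086 cells and 57480919 UMIs (median 7212 UMIs per cell), and the 60TM library 7574 cells and 70610233 UMIs (median 7494.5). Differences are described as higher or lower in the 60TM library, without tests, and intervals are 95% and cover counting error only. Cells of clusters that carry the markers of a class are named after that class, although a shared marker profile does not establish the cell type.

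The comparison of cell classes addresses which cells of the hippocampus were present in what share in the disease model. Astrocytes made up a larger share of the 60TM library, 23.5% (22.6 to 24.5) against 14.7% (13.8 to 15.6) in WT, a ratio of 1.60 (1.47 to 1.73). Oligodendrocytes, the myelinating cells, made up a smaller share, 10.1% (9.41 to 10.8) against 23.3% (22.2 to 24.4), a ratio of 0.433 (0.396 to 0.473). Microglia, the resident immune cells, took 34.2% (33.0 to 35.4) of the WT library and 32.6% (31.6 to 33.7) of the 60TM library, a ratio of 0.955 whose interval of 0.901 to 1.01 includes 1. Shares within a library depend on one another, on dissection, on dissociation and on cell calling, so they are not densities in tissue. Choroid plexus cells, which secrete cerebrospinal fluid, were 0.986% of WT and 3.21% of 60TM cells. OPCs were 1.56% and 2.18%, committed oligodendrocyte precursors 1.5% and 1.16%, endothelial cells 2.10% and 2.47%, and pericytes 1.18% and 0.753%, a ratio of 0.636 that turned to 1.43 when each cell was assigned by its highest marker score. Border macrophages, the macrophages of the brain's meninges and vessels, were 1.33% and 1.60%. Ependymal cells were 2.15% and 0.555%, immature neurons 3.24% and 2.10%, Cajal-Retzius cells 1.63% and 0.924%, and other neurons 1.35% and 1.52%. T or NK cells numbered 8 in WT (0.131%) and 27 in 60TM (0.356%).

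Clusters without a class name held 10.7% of WT and 17% of 60TM cells, under a naming rule set after the data had been seen. They were a cluster led by Frzb (2.35% of WT and 5.04% of 60TM cells), a shallow cluster with microglial genes (1.61% and 3.06%), a cluster of dividing progenitors (2.22% and 1.98%), and shallow clusters with astrocyte genes, 1 led by Aldh1a1 and Gfap (0.838% and 2.93%) and 1 without (2.20% and 1.57%). The others carried pericyte with endothelial markers (0.575% and 1.53%), interneuron progenitor genes of the Dlx family (0.674% and 0.713%), and neutrophil with monocyte markers (0.214% and 0.132%).

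**Figure D1:**
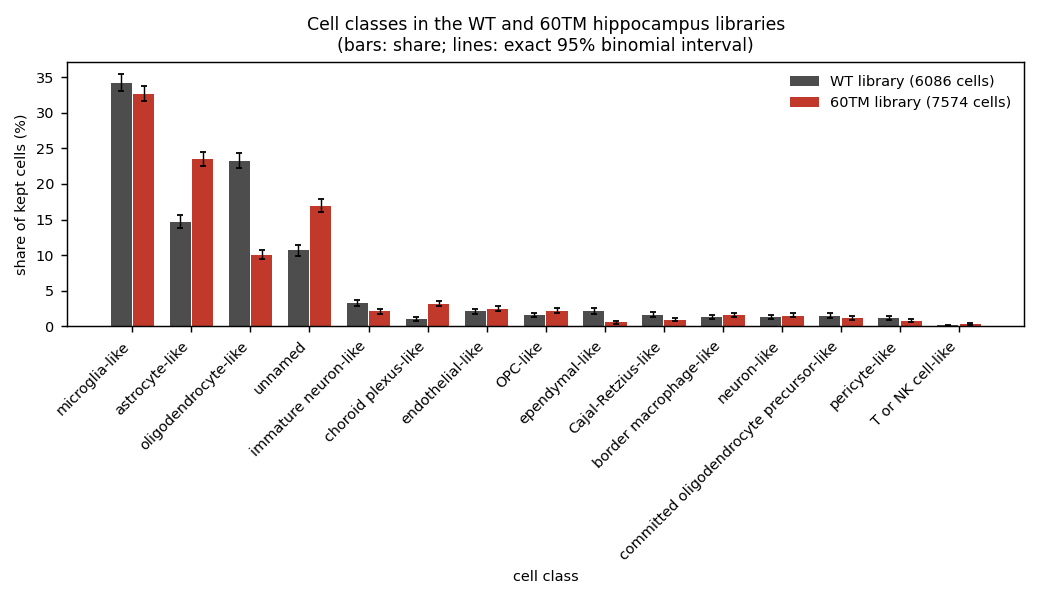
Share of kept cells (%) in each cell class for the WT library (grey, 6086 cells) and the 60TM library (red, 7574 cells), with exact 95% binomial intervals as lines. Astrocyte-like cells are at 14.7% in WT and 23.5% in 60TM, oligodendrocyte-like cells at 23.3% and 10.1%, and microglia-like cells at 34.2% and 32.6%.

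Gfap, which encodes the main intermediate filament protein of astrocytes, served as a check of the labels. The mouse gene (ENSMUSG00000020932) lies on the minus strand of chromosome 11 from 102887336 to 102900912 in GRCm38. Its value is that of reads assigned to mouse Gfap, and whether reads of the human transgene are among them is not given in the sources used here. In astrocytes Gfap stood at 387 CPM (371 to 403) in WT and 1308 CPM (1290 to 1326) in 60TM, a ratio of 3.38 (3.24 to 3.53) from 2275 and 20258 UMIs. After thinning to 2000 UMIs, 34.9% (31.8 to 38.2) of WT and 70.9% (68.7 to 73.0) of 60TM astrocytes had a Gfap UMI. In microglia, which should lack Gfap, these shares were 0.632% and 1.96%. Without thinning the shares were 60.6% and 88.1% in astrocytes and 2.07% and 6.11% in microglia. Median depths were 6156 and 7709 UMIs in astrocytes and 5649 and 6891.5 UMIs in microglia. Gfap was below the astrocyte level but also higher in 60TM in other classes, from 3.77 to 14.1 CPM in microglia, from 13 to 25.6 CPM in oligodendrocytes and from 22.0 to 216 CPM in endothelial cells. In OPCs it was 7.29 CPM in WT and 12.7 CPM in 60TM, a ratio of 1.75 whose interval of 0.603 to 6.14 includes 1. It was 18.3 and 78.8 CPM in neurons, 4.00 and 35.0 CPM in immature neurons, and 5.55 and 250 CPM in pericytes, where it rests on 2 and 47 UMIs. In Cajal-Retzius cells it was 2.33 and 22.7 CPM, from 2 and 13 UMIs. In border macrophages, choroid plexus cells and committed oligodendrocyte precursors the interval of its ratio includes 1. These values outside astrocytes moved with the processing: with free RNA subtracted the ratio was 1.92 in microglia and 1.85 in neurons, 124 in pericytes and 0 in OPCs. With no doublets removed it was 4.21 in oligodendrocytes and 8.0 in OPCs, thinned it was 15.7 in endothelial cells and 3.10 in oligodendrocytes, and it was 5.28 in immature neurons with at least 200 genes and at most 5% mitochondrial UMIs.

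**Figure D2:**
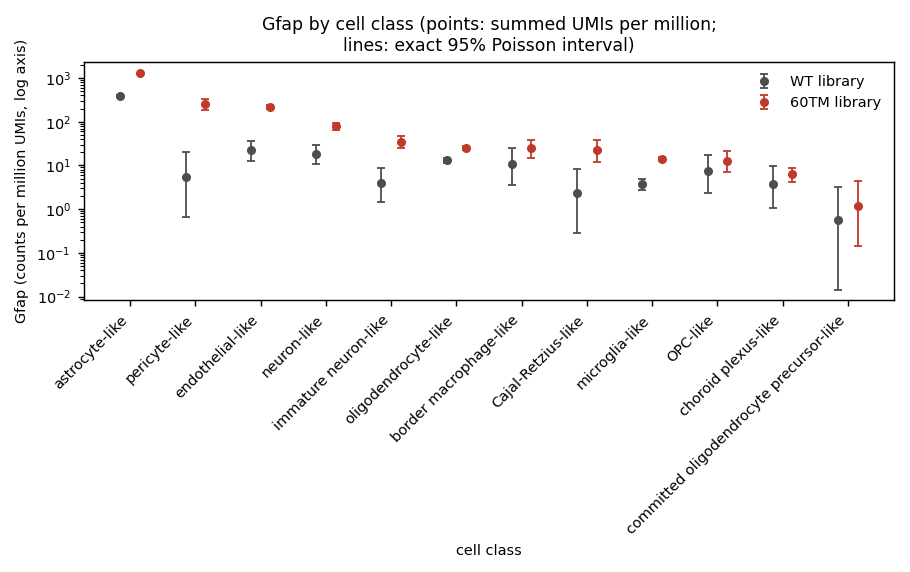
Gfap in CPM (UMIs scaled to the class total, log axis) for each cell class with at least 50 cells in each library, in the WT library (grey) and the 60TM library (red). Lines are exact 95% Poisson intervals. The astrocyte-like class has 387 CPM in WT and 1308 CPM in 60TM, above every other class shown in both libraries. Ependymal cells and T or NK cells are not shown.

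The astrocyte comparison asks how astrocytes, the cells known for making GFAP, differed between the genotypes. Lcn2, an iron-binding acute-phase protein, was far higher in 60TM astrocytes, with 0 UMIs in WT and 1230 CPM in 60TM, at least 2410-fold higher against a floor of 3 UMIs in WT astrocytes. Cxcl10, a chemokine that attracts T cells, stood at 1.36 CPM in WT and 754 CPM in 60TM, a ratio of 554 (281 to 1283). Genes of cholesterol synthesis were lower together, 15 of 16 at a ratio below 1/1.5, and so were 5 of 12 genes of glutamate, potassium and water homeostasis. Of 10571 genes with at least 100 UMIs, 387 were at least 2-fold higher and 126 at least 2-fold lower in 60TM, 513 in all. A part of these values comes from 1 cluster of 448 cells that held 25.2% of 60TM and 0% of WT astrocytes and was led by Lcn2, Cxcl10 and C3. Its cells had a median of 10621 UMIs, against 7498, 7146 and 5102 in the other clusters of 60TM astrocytes. It therefore weighs more in summed UMIs than in cells. Its astrocyte markers had a median log2 ratio to the other clusters of 1.45, against 2.12 to 2.68 in the other astrocyte clusters. With 1 library per genotype, a cluster found in 1 library can be a property of that library. Without this cluster, 172 genes were at least 2-fold different (87 higher and 85 lower of 9835), and the Gfap ratio was 2.17 (2.08 to 2.28). The other astrocytes came mostly from a cluster led by Slc6a11 (52.0% of WT and 24.8% of 60TM astrocytes), a cluster led by Hsd11b1 (18.4% and 46.8%) and a cluster led by Aqp4 and Tnc (29.6% and 3.26%).

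Besides Lcn2 and Cxcl10, the named genes higher in 60TM astrocytes held the chemokines Ccl2, with 1 UMI in WT and 5647 in 60TM (365 CPM, ratio 2143, 384 to 84640), and Cxcl1, with 1 and 977 UMIs (ratio 371, 66.4 to 14656). Icam1, an adhesion molecule that binds leukocytes, had 1 and 774 UMIs (ratio 294, 52.6 to 11614), and Cd70, a ligand of the T cell receptor Cd27, had 2 and 423 UMIs (ratio 80.3, 22.1 to 665). Steap4, a metalloreductase, had 1 and 542 UMIs (ratio 206, 36.8 to 8137), and S1pr3, a receptor for sphingosine 1-phosphate, stood at 1.36 and 71.8 CPM (ratio 52.7, 26.7 to 123). Tgm1, a transglutaminase, had 0 and 411 UMIs, at least 52.0-fold higher against the same floor. Gdf15, a cytokine induced by cell stress, had 2 and 601 UMIs (ratio 114, 31.4 to 944), and Chac1, a glutathione-degrading enzyme of the integrated stress response, had 1 and 410 UMIs (ratio 156, 27.8 to 6159). Ccn5, a matricellular protein, had 1 and 429 UMIs (ratio 163, 29.1 to 6444). These genes depend on the cluster of 60TM cells: it held 97.6% of the 60TM astrocyte UMIs of Lcn2, 95% of those of Cxcl10 and 99.6% of those of Ccl2. Outside it Lcn2 stood at 44.6 CPM, at least 87.4-fold above the WT floor, and Cxcl10 at 57.3 CPM, a ratio of 42.1 (21.2 to 98.0). Of the 12 genes, 10 had a ratio or bound of 2 or more there, and 8 of the 12 an interval above 1, while Gdf15 had a ratio of 1.43 (0.235 to 15.1), Ccn5 of 2.29 (0.227 to 113) and Chac1 of 4.02 (0.516 to 181), with intervals that include 1, and Tgm1 had a bound of 1.53. Ratios over few WT UMIs also moved with other choices of cells: thinned, Ccl2 had 377, Cxcl10 238 and Cxcl1 66.2, Icam1 had 8.74 with no doublets removed, and Steap4 had 709 as a mean over cells. With unnamed clusters added, Icam1 had 43.1, S1pr3 15.4, Gdf15 46.2, Chac1 52.3 and Cd70 35.3. Thinned to 2000 UMIs, 17.4% of 60TM astrocytes had a UMI of Lcn2, against 0 of 867 WT astrocytes, which allows up to 0.346% by a limit of 3 cells and 0.425% by the exact interval. In microglia the thinned share of Lcn2 was 0% in WT and 1.02% in 60TM, and without thinning the astrocyte shares were 0% and 24.7%.

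The named genes lower in 60TM astrocytes lay between 2.69-fold and 7.00-fold, and all 12 stayed at least 2-fold lower without the cluster of 60TM cells. Myoc, a secreted glycoprotein, stood at 73.7 CPM in WT and 10.5 CPM in 60TM, 7.00-fold lower (5.83 to 8.44), but 2.76-fold lower with at least 200 genes and at most 5% mitochondrial UMIs per cell. Gdf10, a ligand of the TGF-beta family, was 4.74-fold lower, and Agt, the precursor of angiotensin, was 2.69-fold lower (2.55 to 2.84), from 471 CPM to 175 CPM. The receptors Gabbr2, a subunit of the GABA-B receptor, and Grin3a, a subunit of the NMDA receptor, were 3.25-fold and 3.27-fold lower. Dhcr7, which makes cholesterol in its last step, was 2.95-fold lower (2.64 to 3.31), from 112 to 38.0 CPM. Rhcg, an ammonium transporter, was 3.80-fold lower, Padi2, which turns arginine of proteins into citrulline, 3.85-fold, and Col11a2, a collagen, 3.09-fold. Hhatl was 4.08-fold lower, Sned1 3.69-fold and Fam184b 3.53-fold. Hhatl and Col11a2 are among the leading genes of the cluster with Aqp4 and Tnc, whose share of the class was 29.6% in WT and 3.26% in 60TM. Agt is among those of the cluster led by Slc6a11, whose share was 52.0% in WT and 24.8% in 60TM. Whether these shares account for the lower values was not tested.

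Reactive astrocyte genes were higher as a group in 60TM astrocytes: all 15 measured members reached a ratio of 1.5, with a median log2 ratio of 2.47 (2.35 to 2.61) at percentile 100 of matched random lists. Vim, an intermediate filament partner of Gfap, had a ratio of 6.11, Cp, the copper-binding ferroxidase ceruloplasmin, rested on 4 and 726 UMIs with a ratio of 68.9, and Serpina3n, a protease inhibitor, stood at 9.53 and 75.7 CPM. Without the cluster of 60TM cells, and over the same members as with it here and below, the list's median was 1.07, Vim had a ratio of 1.85 and Serpina3n of 2.92. The list of A1 genes, named after astrocytes exposed to microglial cytokines, had 10 of 11 members higher and a median of 1.27, and 0.77 without the cluster. Its member Gbp2, an interferon-induced GTPase, had a ratio of 14.7 and Serping1, a complement inhibitor, of 7.59. The list of A2 genes, named after astrocytes in ischaemia, had 7 of 8 higher and a median of 0.71, or 0.12 without the cluster, with Ptx3 at a ratio of 10.6 and Cd14 at 12.4. The Nrf2 targets, which answer oxidative stress, had 10 of 14 higher and a median of 0.81, or 0.33 without the cluster. Among them Hmox1, which degrades haem, stood at 8.85 and 119 CPM (ratio 13.4), and at 13.2 CPM in 60TM outside the cluster (ratio 1.49), and Srxn1 had a ratio of 5.32. Chaperones had 7 of 13 higher and a median of 0.36, or 0.14 without the cluster, with the small heat shock genes Hspb1 at a ratio of 35.9 and Hspb6 at 4.03, and Hspa8 at 1.25. Metallothioneins and iron handling genes had 3 of 9 higher and a median of 0.34. The ferritin chains Fth1 and Ftl1 had ratios of 3.44 and 2.99, and 2.24 and 2.01 without the cluster. The other examples were lower there too: without the cluster Cp had a ratio of 13.3, Serping1 of 3.76, Ptx3 of 2.01, Cd14 of 4.93, Srxn1 of 1.57, Hspb1 of 6.02, Hspb6 of 2.45 and Hspa8 of 1.18. Gbp2 had 1.41 with an interval of 0.721 to 2.93 that includes 1, the cluster having held 93.7% of its 60TM UMIs.

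Immune signalling lists were higher in 60TM astrocytes as well. Interferon response genes had 16 of 17 members higher and a median of 1.27 (1.17 to 1.45), or 0.72 without the cluster of 60TM cells. Isg15, a ubiquitin-like antiviral protein, had 3 UMIs in WT and 658 in 60TM, and Ifitm3, which blocks virus entry, stood at 38.0 and 217 CPM, a ratio of 5.73, and of 3.16 without the cluster. MHC class I genes, which present peptides to T cells, had 10 of 10 higher and a median of 1.08, or 0.26 without the cluster, with H2-D1 at a ratio of 3.49, and of 1.97 (1.71 to 2.29) without the cluster. Complement, cytokine and trophic factor genes had 10 of 15 higher and 2 lower, with a median of 0.74, or 0.06 without the cluster. The central complement gene C3 stood at 8.68 CPM in WT and 119 CPM in 60TM, a ratio of 13.7, but the cluster held 97.3% of its 60TM UMIs and outside it C3 was at 4.88 CPM, 1.78-fold lower than in WT. C4b, an early complement component, had a ratio of 4.89, and of 3.68 (3.24 to 4.20) without the cluster. NF-kB targets and inflammatory cytokines had 10 of 10 higher and a median of 1.17, or 0.38 without the cluster and 3.60 when thinned, with Nfkbia, the inhibitor induced by NF-kB itself, at a ratio of 4.25. Immediate early and dissociation genes had 16 of 16 higher and a median of 1.29 (1.22 to 1.41), or 0.78 without the cluster, with Fos at 22.1 and 270 CPM and Junb at a ratio of 19.6. Without the cluster Junb had a ratio of 8.05, Fos of 9.23, Nfkbia of 2.43 and Isg15 of 16.3 (5.38 to 80.4). Since these genes respond to tissue handling, their higher level stands beside every immune list of this class.

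Genes of cholesterol synthesis had 0 of 16 members higher and 15 lower in 60TM astrocytes, with a median log2 ratio of −0.98 (−1.01 to −0.92) at percentile 0, and −0.85 without the cluster of 60TM cells. Hmgcs1, an early enzyme of the pathway, had a ratio of 0.501, Fdps of 0.389 and Msmo1, a sterol oxidase, of 0.439. Genes of glutamate, potassium and water homeostasis had 0 of 12 higher and 5 lower, with a median of −0.55 (−0.57 to −0.53) at percentile 0, and −0.34 without the cluster. Gja1, the gap junction protein connexin 43, stood at 2937 and 1564 CPM, a ratio of 0.532. Slc1a2, the main glutamate transporter, had a ratio of 0.675, or 0.814 without the cluster, and Slc7a10, which carries serine and glycine, had 0.575. Glul, which turns glutamate into glutamine, had a ratio of 0.896, but 1.04 without the cluster, where Gja1 had 0.635 and Slc7a10 0.765. Slc6a11, Slc7a10 and Gjb6 of this list are leading genes of the astrocytes with Slc6a11, whose share of the class was 52.0% in WT and 24.8% in 60TM. Whether this share accounts for the lower values was not tested. Astrocyte purinergic genes went both ways, with 2 of 11 higher and 3 lower and a median of −0.14 at percentile 10.9. Entpd2, an ectonucleotidase that degrades ATP, was at 174 CPM in WT and 91.3 CPM in 60TM, a ratio of 0.524. Its thinned share of astrocytes with a UMI was 30.7% and 16.3%, against 0.0973% and 0.0408% in microglia, and 60.2% and 49.1% of astrocytes without thinning. Alpl, a phosphatase that also degrades nucleotides, had a ratio of 0.364, and Panx1, a channel that releases ATP, of 4.23, but of 0.82 (0.282 to 2.54) without the cluster. Synaptogenic and matrix genes had a median of −0.21 (percentile 1.97) with 3 of 15 higher and 3 lower, and Ncan, a proteoglycan of the matrix, had a ratio of 0.471.

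Of the remaining lists in astrocytes, calcium handling genes had a median of −0.13, the unfolded protein and integrated stress response 0.03, the proteasome 0.16 and autophagy −0.01. Within the stress response list Asns, which makes asparagine, had a ratio of 41.7, and of 2.73 (0.906 to 11) without the cluster, and Chac1 is named above. Lists of other cell types had medians of 0.25 for homeostatic microglia, 0.20 for disease-associated microglia, −0.10 for microglia purinergic receptors, −0.04 for phagocytosis and lysosome, −0.19 for myelin (0.71 with free RNA subtracted), −0.07 for OPC differentiation, 0.60 for disease-associated oligodendrocytes (0.26 without the cluster of 60TM cells), 0.05 for the blood-brain barrier and 0.13 for proliferation. Endothelial activation had 3.41 over 3 measured members, 0.56 without the cluster, 2.37 with no doublets removed and 1.56 with unnamed clusters added, among them Lcn2 and Icam1, which the reactive and named genes above also hold. By the markers of other classes, free RNA made up 1.45% of UMIs in WT and 2.27% in 60TM astrocytes, and the directions of both microglia lists turned when no doublets were removed.

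The microglia comparison asks how the immune cells next to the altered astrocytes differed. Interferon response genes were higher in 60TM microglia, 17 of 18 at a ratio of 1.5 or more, with a median log2 ratio of 1.88 (1.77 to 1.99) at percentile 100. Disease-associated microglia genes, which microglia express in models of neurodegeneration, were lower as a group, with 1 of 22 higher and 8 lower and a median of −0.32 (−0.36 to −0.30) at percentile 0. Homeostatic microglia genes were slightly lower, with a median of −0.16 (−0.20 to −0.15) and 0 of 15 past a ratio of 1.5 in either direction. Of 10209 genes, 96 were at least 2-fold higher and 30 at least 2-fold lower in 60TM, 126 in all. The class held 4 clusters: 1 led by P2ry12 (49.8% of WT and 28.5% of 60TM microglia), 1 led by the immediate early genes Rgs1, Zfp36 and Jun (32.2% and 24.5%), 1 led by Ccl4, Atf3 and Fosb (15.8% and 34.0%), and 1 led by Ifi204 and other interferon genes (2.21% and 13%). Whether the last cluster accounts for the higher interferon genes of the class was not tested.

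The named genes higher in 60TM microglia included Ifi204, a sensor of DNA, at 4.76 and 78.7 CPM (ratio 16.5, 12.9 to 21.7), Isg15 at 4.76 and 54.1 CPM (11.4, 8.82 to 14.9), Ifit3 at 5.51 and 60.8 CPM (11, 8.71 to 14.2), Ifit2 (15.2, 10.8 to 21.9), Ifit3b (14.5), Oasl2 (15.6, 10.4 to 24.3), Zbp1, a sensor of nucleic acids (17, 9.35 to 34.5), Ifi27l2a (8.80, 7.94 to 9.78), Irf7, which drives interferon genes (10.1, 7.02 to 14.9), and the chemokine Ccl12, at 94.8 and 548 CPM (5.78, 5.45 to 6.14). Zbp1 had a ratio of 47.8 when thinned and 10 with at least 200 genes and at most 5% mitochondrial UMIs. Ifit3 and Ifit3b are paralogs that can share reads. Naip6, of a family of bacterial sensors, had 0 UMIs in WT and 317 in 60TM, at least 74.8-fold higher against a floor of 3 UMIs in WT microglia, and Gm16867 had 0 and 160 UMIs, at least 37.8-fold. Gm16867 also had 0 UMIs in WT and 41 in 60TM astrocytes, and 0 and 12 in oligodendrocytes, so its difference was not particular to microglia. Thinned to 2000 UMIs, 1.02% of WT and 6.08% of 60TM microglia had an Ifit3 UMI, and 2.31% and 13.3% without thinning. In oligodendrocytes the thinned Ifit3 shares were 0.142% and 0.264%, at median depths of 14592 and 15566 UMIs. Within the interferon list, Bst2, which holds back virus release, had a ratio of 2.09 and Lgals3bp of 2.30.

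The named genes lower in 60TM microglia lay between 1.71-fold and 3.60-fold. Lgals3, a galectin of activated phagocytes, was 3.29-fold lower (2.65 to 4.12), at 21.1 and 6.41 CPM, and 1.81-fold lower when thinned. Lpl, which breaks down lipoprotein fat, was 2.49-fold lower (2.24 to 2.76), Abcg1, a cholesterol exporter, 1.77-fold, and Cd9, a tetraspanin, 1.71-fold (1.67 to 1.75), from 1312 to 767 CPM. Fam20c, a kinase of secreted proteins, was 3.60-fold lower, Angptl7 2.64-fold, the histone gene Hist1h2ac 2.40-fold and Il4i1, an amino acid oxidase, 2.13-fold. G530011O06Rik was 2.14-fold and Gm49980 2.24-fold lower. The paralogs Rnaset2a and Rnaset2b, 1.98-fold and 2.01-fold lower, can share reads, so their values are uncertain. In the disease-associated list Spp1, a secreted phosphoprotein, had a ratio of 0.145, at 45.7 and 6.63 CPM, and Trem2, a lipid receptor, of 0.825, while Axl, a receptor for dying cells, had 1.61. Of the homeostatic genes, P2ry12, the receptor by which microglia sense ADP, stood at 3292 CPM in WT and 2400 CPM in 60TM, a ratio of 0.729. Nearly every microglial cell had a P2ry12 UMI, 98.1% in WT and 97.3% in 60TM thinned, and 99.8% and 99.7% without thinning, against 1.21% and 1.06% of oligodendrocytes thinned. Cx3cr1, the fractalkine receptor, had a ratio of 0.832, Tgfbr1 of 0.725 and Cst3 of 0.784.

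Immediate early and dissociation genes had 7 of 18 members higher and 1 lower in 60TM microglia, with a median of 0.49 (0.46 to 0.50). Klf2 stood at 467 and 1060 CPM (ratio 2.27), Socs3, an inhibitor of cytokine signalling, had a ratio of 2.21, Dusp1 of 1.73 and Jun of 1.38. NF-kB targets and cytokines had 6 of 16 higher and 2 lower and a median of 0.24. Cxcl10 had a ratio of 9.47 and Ccl2 of 4.14, while Ccl4 was lower at 0.724. MHC class I genes had 3 of 10 higher and a median of 0.29, with H2-D1 at a ratio of 1.95 and H2-K1 at 1.71. MHC class II genes had 0 of 4 higher, 1 lower and a median of −0.01. The MHC class II median was 0.37 with no doublets removed and 0.20 with at least 200 genes and at most 5% mitochondrial UMIs. Complement, cytokine and trophic factor genes had 7 of 13 higher and a median of 0.16, among them C4b with 6 UMIs in WT and 366 in 60TM, a ratio of 43.2. Proliferation genes had 7 of 11 higher and a median of 0.33, with Mcm6, part of the replicative helicase, at a ratio of 2.24. The A1 genes had a median of 0.40, with Iigp1, an interferon-induced GTPase, at a ratio of 21.4, and chaperones 0.25. Phagocytosis and lysosome genes had a median of −0.14, microglia purinergic receptors −0.12 and autophagy −0.17. Other medians in microglia were 0.14 for reactive astrocyte genes, −0.18 for A2 genes, 0.01 for Nrf2 targets, 0.03 for metallothioneins and iron, 0.15 for glutamate, potassium and water homeostasis, −0.02 for astrocyte purinergic genes, 0.04 for calcium handling, 0.09 for cholesterol synthesis, 0.14 for synaptogenic genes, 0.08 for the unfolded protein response, 0.07 for the proteasome, 0.03 for the blood-brain barrier, 0.66 for endothelial activation, −0.10 for myelin, 0.20 for disease-associated oligodendrocytes and −0.03 for OPC differentiation. The directions of the reactive astrocyte and homeostasis lists in microglia turned under some alternatives. Those of some other lists turned too, such as metallothioneins and iron (−0.41) and synaptogenic genes (−0.12), both with free RNA subtracted.

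**Figure D3:**
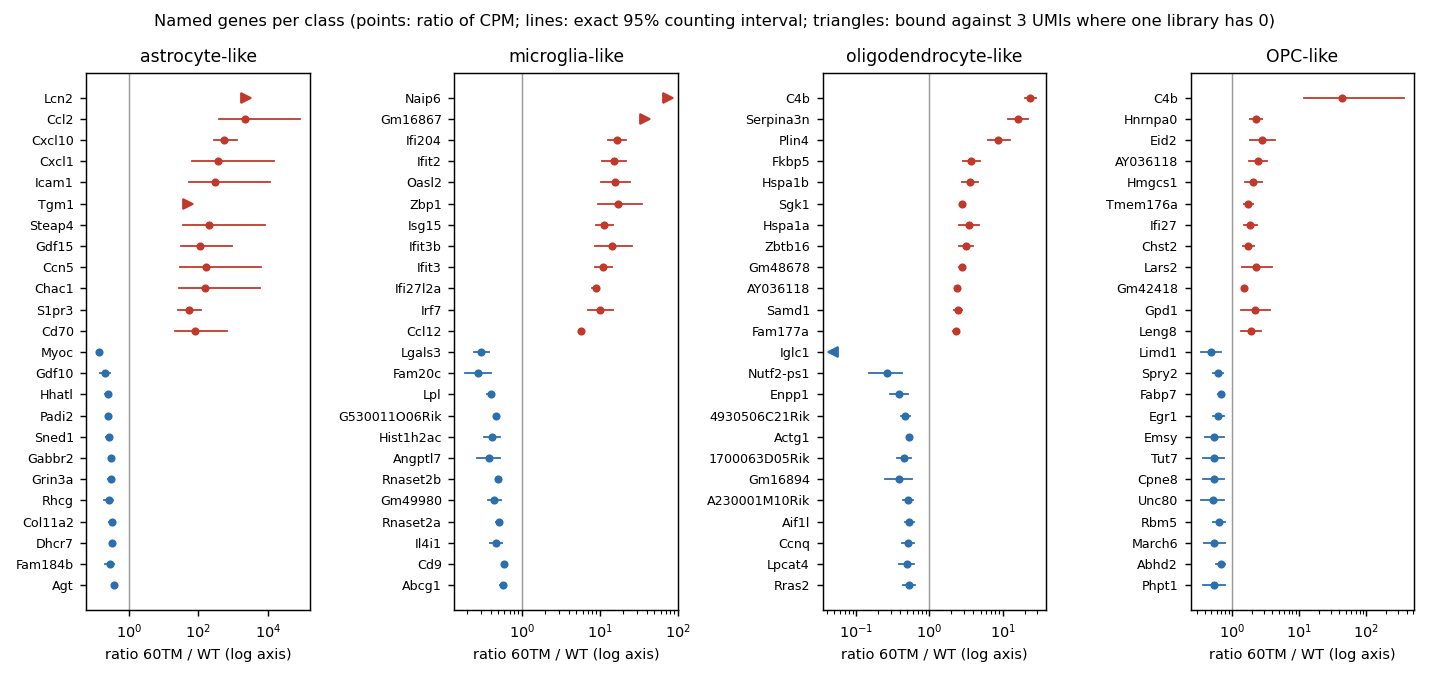
Ratio of CPM in 60TM over WT (log axis) for the 12 highest (red) and 12 lowest (blue) named genes in astrocyte-like, microglia-like, oligodendrocyte-like and OPC-like cells, with exact 95% counting intervals as lines and triangles for bounds where a library has 0 UMIs. Ratios reach over 100 in astrocytes for Ccl2, Cxcl10 and Cxcl1, while the named genes of OPCs other than C4b stay below a ratio of 3.

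The oligodendrocyte comparison asks whether myelinating cells differed beside their smaller share. The complement gene C4b and the protease inhibitor gene Serpina3n were higher in 60TM oligodendrocytes: C4b stood at 5.54 CPM in WT and 133 CPM in 60TM, a ratio of 23.9 (20.0 to 28.8), and Serpina3n at 1.93 and 31.0 CPM, a ratio of 16.0 (11.8 to 22.3). Myelin genes stayed near equal as a group, with 0 of 12 past a ratio of 1.5 in either direction and a median of −0.06 at percentile 24.1. Of 9967 genes, 75 were at least 2-fold higher and 25 at least 2-fold lower, 100 in all. The same 5 clusters made up the class at similar shares, the largest holding 40.9% of WT and 41.3% of 60TM oligodendrocytes and the next 31.2% and 25%.

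Among the other named genes higher in 60TM oligodendrocytes, Plin4, a coat protein of lipid droplets, stood at 1.72 and 15.1 CPM (ratio 8.79, 6.25 to 12.7). Sgk1, a kinase induced by glucocorticoids, was at 157 and 436 CPM (2.78, 2.67 to 2.90), Fkbp5, which holds back the glucocorticoid receptor, at a ratio of 3.71, and Zbtb16, a transcription factor, at 3.16. The heat shock genes Hspa1a and Hspa1b, paralogs that can share reads, had ratios of 3.46 and 3.58. Samd1 had a ratio of 2.45, Fam177a of 2.33, AY036118 of 2.38 and the antisense gene Gm48678 of 2.77. AY036118 overlaps ribosomal RNA repeats, so the origin of its reads is uncertain. Gm48678 is uncertain too, since reads of an overlapping gene can be assigned to it. Thinned to 2000 UMIs, 0.923% of WT and 16.0% of 60TM oligodendrocytes had a C4b UMI, against 0.0486% and 3.26% of microglia, and 6.28% and 39.1% of oligodendrocytes without thinning. On the lower side, Iglc1, an immunoglobulin light chain gene, had 106 UMIs in WT and 0 in 60TM, at least 21.0-fold lower against a floor of 3 UMIs in 60TM oligodendrocytes. Nutf2-ps1, which the annotation lists as protein-coding, was 3.85-fold lower, Enpp1, an ectonucleotidase, 2.58-fold, and the cytoskeletal gene Actg1 1.88-fold (1.82 to 1.95), from 595 to 316 CPM. Aif1l was 1.87-fold lower, Ccnq 1.98-fold, Lpcat4, an enzyme of phospholipid remodelling, 2.04-fold and Rras2, a small GTPase, 1.92-fold, but Rras2 had a ratio of 1.0 when no doublets were removed. The non-coding genes 4930506C21Rik, 1700063D05Rik and A230001M10Rik were 2.13-fold, 2.21-fold and 1.97-fold lower, and the antisense gene Gm16894 2.60-fold, with the same uncertainty. Thinned, Nutf2-ps1 and Gm16894 had 0 UMIs in 60TM oligodendrocytes, and Hspa1a had a ratio of 2.20.

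Disease-associated oligodendrocyte genes had 5 of 10 members higher, 0 lower and a median of 0.42 (0.34 to 0.54) in 60TM oligodendrocytes. Its members B2m and H2-D1 had ratios of 2.75 and 3.68, while Il33, an alarmin, had 0.675. MHC class I genes had 5 of 8 higher and 1 lower and a median of 0.39, or 1.45 when thinned, with H2-T23 at a ratio of 3.52. Interferon response genes had 9 of 16 higher and 2 lower and a median of 0.17 (0.10 to 0.27), with Ifi27l2a at a ratio of 6.85. Immediate early and dissociation genes had 11 of 17 higher and a median of 0.53 (0.36 to 0.61), with Junb at a ratio of 2.94 and Fos at 2.79. Of the myelin genes, Mbp had a ratio of 1.06, Mobp of 1.22 and Aspa of 0.818. Reactive astrocyte genes had a median of 0.69 and A1 genes of 0.92, over 9 and 5 measured members that include Serpina3n and H2-D1, and the A1 median was 1.67 when thinned. Chaperones had a median of 0.28, the unfolded protein response 0.11, with Hspa5 at a ratio of 1.70, the proteasome 0.14, Nrf2 targets 0.23, metallothioneins and iron 0.14, complement 0.23 and NF-kB targets 0.29. Astrocyte purinergic genes had 3 of 7 lower and a median of −0.33. The other medians were: cholesterol synthesis 0.00, A2 genes 0.00, OPC differentiation −0.03, autophagy −0.05, proliferation −0.06, calcium handling 0.15, homeostasis 0.16, homeostatic microglia 0.11, disease-associated microglia 0.08, phagocytosis −0.02 and blood-brain barrier 0.01. The direction of the homeostatic microglia list in oligodendrocytes turned when no doublets were removed.

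The OPC comparison asks the same of the precursors of oligodendrocytes, with 95 cells in WT and 165 in 60TM, all in 1 cluster. C4b again led the named genes, with 2 UMIs in WT and 152 in 60TM, a ratio of 44.2 (12 to 369), or 22.3 when thinned. Interferon response genes were higher, with 8 of 9 members past a ratio of 1.5 and a median of 1.36 (0.85 to 1.82), and cholesterol synthesis genes were higher, with 6 of 16 and a median of 0.45 (0.29 to 0.63), unlike in astrocytes. Genes of OPC differentiation stayed near equal as a group, with 1 of 12 higher and 1 lower and a median of −0.04. Of 4110 genes, 10 were at least 2-fold higher and 2 at least 2-fold lower, 12 in all. The smaller number of UMIs in this class, 685652 in WT and 1178087 in 60TM, limits how many genes can be compared.

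Named genes higher in 60TM OPCs were Hmgcs1, an enzyme of cholesterol synthesis, at 93.3 and 195 CPM (ratio 2.09, 1.58 to 2.80), Hnrnpa0, an RNA-binding protein (2.30, 1.90 to 2.79), Eid2, a repressor of differentiation (2.85, 1.90 to 4.41), Ifi27, an interferon-induced gene (1.87), Gpd1, an enzyme of glycerol metabolism (2.25), Lars2, a mitochondrial tRNA ligase (2.30), Tmem176a (1.77), the sulfotransferase Chst2 (1.76), Leng8 (1.91), AY036118 (2.47) and Gm42418 (1.54). The last pair overlaps ribosomal RNA repeats and so reads with uncertain origin. Named genes lower were Fabp7, a fatty acid binding protein, 1.46-fold from 1154 to 792 CPM, Spry2, an inhibitor of growth factor signalling, 1.61-fold, Egr1, an immediate early gene, at 331 and 209 CPM, Limd1 2.05-fold (1.46 to 2.88), Emsy 1.80-fold, Tut7 1.86-fold, Cpne8 1.86-fold, Unc80 1.92-fold, Rbm5 1.56-fold, March6 1.83-fold (3.04-fold when thinned), Abhd2 1.47-fold and Phpt1 1.83-fold. Thinned to 2000 UMIs, 1.1% of WT and 16.6% of 60TM OPCs had a C4b UMI, against 0.0486% and 3.26% of microglia, at median depths of 6968 and 7350 UMIs in OPCs. The OPC shares were 2.11% and 31.5% without thinning.

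Among the OPC lists, Ifit3 had a ratio of 5.09, and Ifit1 rested on 2 and 45 UMIs. Mvd and Idi1, enzymes of cholesterol synthesis, had ratios of 2.17 and 1.65. Disease-associated oligodendrocyte genes had 4 of 7 higher and a median of 0.58, with Serpina3n at a ratio of 2.10, and MHC class I genes 3 of 7 and 0.41. Immediate early and dissociation genes had 1 of 12 higher and 5 lower, with a median of −0.16 (−0.44 to 0.00) and Fosb at a ratio of 0.416. Proliferation genes had a median of −0.35 with 1 of 8 higher and 2 lower, and myelin genes of 0.24 with 3 of 10 higher. The unfolded protein response had a median of 0.20 and the proteasome of 0.16, reactive astrocyte genes 0.32 and A1 genes 0.37, the last −0.027 when no doublets were removed. Olig2, a transcription factor of the lineage, had a ratio of 0.930.

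**Figure D4:**
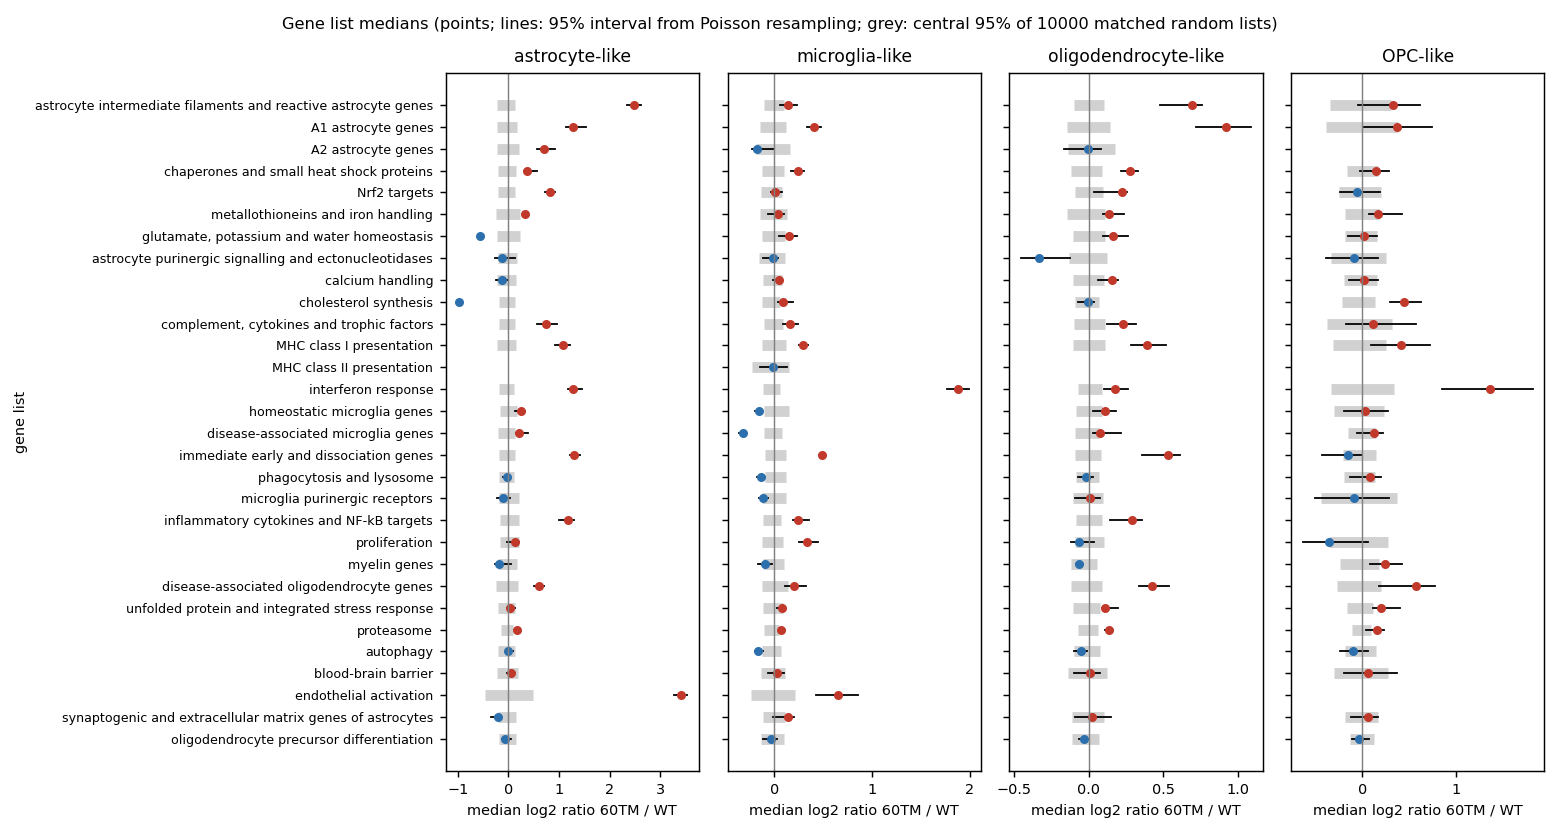
Median log2 ratio of 60TM over WT for the gene lists in astrocyte-like, microglia-like, oligodendrocyte-like and OPC-like cells (points, red above 0 and blue below), with 95% Poisson resampling intervals as lines and the central 95% of 10000 matched random lists in grey. The interferon list lies at 1.27, 1.88, 0.17 and 1.36 in the 4 classes, and cholesterol synthesis at −0.98 in astrocytes and 0.45 in OPCs.

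Other classes with at least 50 cells in each library are given as summaries. Endothelial cells had 38 genes at least 2-fold higher and 11 lower of 3457, blood-brain barrier genes had a median of −0.02 with 0 of 11 past a ratio of 1.5, and endothelial activation genes, which recruit leukocytes, had 4 of 7 higher, 1 lower and a median of 0.86 (0.41 to 1.1). Astrocyte markers were higher in endothelial cells too, at 381 CPM in WT and 699 CPM in 60TM, with free RNA at 3.96% and 5.54%, and the list holds Lcn2, which leads the astrocyte cluster of 60TM cells. Border macrophages, with 81 and 121 cells, had 39 genes higher and 14 lower of 1885. Choroid plexus cells, with 60 and 243 cells, had 93 higher and 31 lower of 4965, immature neurons 6 and 1 of 4537, neurons 48 and 50 of 5093, Cajal-Retzius cells 7 and 4 of 2782, committed oligodendrocyte precursors 10 and 3 of 5231, and pericytes 19 and 47 of 879. In the 4 main classes, no scaling alternative moved the median log2 ratio of all genes counted by more than 0.1.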

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

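Of the tests in this part, the shares of the interferon excess that other immune cells' markers and free RNA bring and the comparison with OPCs were chosen only after the results were seen. Signals stood above the WT level in cells that no comparison used. In cells of unnamed clusters, Gfap was at 668.7 CPM in 60TM against 172 in WT, a ratio of 3.88 (3.60 to 4.19). Lcn2 was at 44.4 CPM there against 10.4 in WT, a ratio of 4.26, and Cxcl10 at 65.2 CPM against 0 UMIs in WT, at least 95.9-fold higher over a floor of 3 UMIs. In barcodes removed by the filters, 775 in WT and 1159 in 60TM, Gfap was at 396 CPM in 60TM against 75.7 in WT, a ratio of 5.24. Lcn2 was at 232 CPM among them against 0 UMIs in WT, at least 468-fold higher, and Cxcl10 at 89.2 CPM against 6 UMIs in WT, a ratio of 90 (41.2 to 246).

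The first pattern is the higher Lcn2, Cxcl10 and C3 in 60TM astrocytes, which rests on a cluster of 448 cells found in the 60TM library alone. Microglial RNA or doublets with microglia would leave these genes higher in microglia, but the median log2 ratio of 60TM astrocytes over 60TM microglia was 6.66, and the lowest of the 3 genes' lower bounds was 4.4. Doublets with other classes were not tested. Depth alone would leave no difference at equal depth. At 2000 UMIs per cell the ratio of the shares with an Lcn2 UMI had a lower bound of 40.6. WT astrocytes had 0 Lcn2 UMIs before thinning, however, so their share could only be 0. At the same depth, 0.346% of WT and 15.5% of 60TM astrocytes had a Cxcl10 UMI, and 0.231% and 8.54% a C3 UMI. These shares argue against depth as the whole cause for Cxcl10 and C3. A response to dissociation would raise the immediate early genes as much, but their median log2 ratio in astrocytes was 1.29 against 6.90 for the 3 genes. The 6.90 is the value of Cxcl10, and the 3 genes lead the cluster, so leading genes are set against the centre of a list. Such a comparison cannot decide whether dissociation is the cause for Lcn2 and Cxcl10. For C3, whose ratio was lower than that of Junb from that list, it cannot decide either. A state of astrocytes in the 60TM mice is a hypothesis that 1 library per genotype leaves untested against an event in 1 of the pooled mice or in the handling of this library, and the values do not separate these.

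The second pattern is the higher interferon response genes in 60TM microglia, with a median log2 ratio of 1.88. Other immune cells in the class would raise their own markers as much, but the summed UMIs of 17 such markers had a log2 ratio of −0.13. Since Ighm and Cd79b have a high level in WT microglia, the 15 markers under 5 CPM were also summed. These were higher, with 67 UMIs in WT and 261 in 60TM, and their excess would bring 0.294% (up to 0.521%) of the interferon genes' excess. Most of these UMIs came from the monocyte markers Plac8 (19 in WT and 171 in 60TM) and Ccr2 (41 and 78). Scaled to the class totals, Plac8 had a ratio of 6.37 (3.96 to 10.8). That of Ccr2 was 1.35, with an interval of 0.912 to 2.02 that includes 1. The 0.294% rests on the summed level of all 15 markers in T or NK cells and the neutrophil with monocyte cluster. It therefore cannot exclude monocyte-like cells that carry mainly Plac8. Free RNA of the 60TM suspension would raise these genes in oligodendrocytes, where the median was 0.17, but these hold only 1.08% free RNA, and the list was also higher in astrocytes (1.27), OPCs (1.36) and border macrophages (1.46), so the share was computed too: at 2.26% free RNA in 60TM microglia, RNA with the level of the 60TM cluster highest in these genes would bring 14.6% (up to 15%) of their excess. Monocyte-like cells in the class stay open. So does, as a hypothesis, an interferon response of microglia in the 60TM mice or in some of the 3 pooled mice, which 1 library per genotype cannot test.

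The third pattern is the higher immediate early and dissociation genes in 60TM microglia, with a median log2 ratio of 0.49. A stronger dissociation response of the whole 60TM suspension was tested on oligodendrocytes, OPCs and endothelial cells. Of these, oligodendrocytes had the largest median, 0.53, as high as in microglia, but it ranged from 0.23 to 0.66 over the alternatives. This response and one of microglia to the genotype therefore cannot be told apart. Outside the test, the list had a median of 1.29 in astrocytes and 0.97 in choroid plexus cells, above that in microglia. In border macrophages it was 0.24 and in immature neurons 0.15. A response shared alike by every class is argued against by OPCs, with a median of −0.16 (upper bound 0.00), or 0.018 with no doublets removed, and the median in endothelial cells was −0.05. A dissociation response that some classes mount more strongly stays open. Genotype and library are the same split here, so a biological difference stays open as well, untested.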

How the results depend on the processing

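The alternatives without the cluster of 60TM cells and with unnamed clusters added were chosen only after the results were seen. Over 240 results and 2480 alternative values, 2105 were the same within counting error or, for gene counts, within 1.5 times, 364 moved and 11 reversed. A result counts as reversed where its interval lay on 1 side of no difference (for lists, with the median also outside the central 95% of random lists) and the alternative turned its direction. Of the class shares, 112 values were the same, 4 moved and 1 reversed. Of the gene ratios, 842 were the same, 98 moved and 1 reversed, and of the list medians 1116, 241 and 9. The oligodendrocyte share ratio stayed between 0.433 and 0.457, the astrocyte one between 1.41 (each library clustered alone) and 1.69, and the microglia one between 0.940 and 1.06 (at least 200 genes and at most 5% mitochondrial UMIs), across 1. The Gfap ratio in astrocytes was 2.95 with mean per-cell CPM, 3.06 thinned, 4.74 with the same joint filter on genes and mitochondrial UMIs, 2.17 without the cluster and 3.21 with unnamed clusters, and the ratio of its shares of cells was 2.35 at 1000 UMIs and 1.46 unthinned. Gene counts at 2-fold were lower where fewer genes or UMIs were used: thinned 204 in astrocytes, 68 in microglia, 29 in oligodendrocytes and 3 in OPCs, and with a minimum of 300 UMIs 290, 69, 43 and 2. With a minimum of 50 UMIs they were 221 in microglia, 185 in oligodendrocytes and 66 in OPCs. Without the cluster the astrocyte count was 172. With no doublets removed the count was 199 in oligodendrocytes and 23 in OPCs, and with mean per-cell CPM 22 in OPCs, where the cause was not tested. The reactive astrocyte list in astrocytes had a median of 2.06 with mean CPM, 2.11 thinned, 1.09 without the cluster (over the 14 members with enough UMIs there), 2.12 with unnamed clusters, 3.86 with CPM + 1 and 1.69 with CPM + 20. Cholesterol synthesis there was −0.91 with mean CPM, −0.92 thinned, −0.91 with that joint filter, −0.85 without the cluster, −0.88 with unnamed clusters and −0.91 with CPM + 20. Interferon genes in microglia were 1.72 thinned, 2.73 with CPM + 1 and 1.02 with CPM + 20, and those in astrocytes 2.22 with CPM + 1 and 0.60 with CPM + 20. Homeostatic microglia genes in microglia were −0.12 with each of the TMM factors, totals without mitochondrial and ribosomal protein genes, and medians of ratios. Disease-associated oligodendrocyte genes in oligodendrocytes were 0.63 with mean CPM, 0.71 thinned and 0.32 with CPM + 20. The 5 lists given here in full were picked after the values were seen. Reversed were the pericyte share ratio, 1.43 by per-cell marker score; Rras2 in oligodendrocytes, 1.0 with no doublets removed; homeostatic microglia genes in astrocytes, −0.26 with no doublets removed, −0.17 with free RNA subtracted and −0.063 over members with 100 UMIs, and in oligodendrocytes −0.016 with no doublets removed; disease-associated microglia genes in astrocytes, −0.057 with no doublets removed; and in microglia the reactive astrocyte list, −0.14 with free RNA subtracted and −0.022 over members with 100 UMIs, and the homeostasis list, −0.031 thinned and −0.68 with free RNA subtracted. Turns of lists inside that random range, such as OPC differentiation in oligodendrocytes (0.051 with no doublets removed), metallothioneins in OPCs (−0.090 with free RNA subtracted) and myelin in microglia (0.24 with free RNA subtracted), count as moved. Apart from the counts with fewer genes or UMIs, the cause was not tested. Depth limits OPCs, which have the fewest UMIs of the 4 main classes, and no paired analysis was possible because each genotype has 1 library.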

Other observations

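The genes of this part and the list of glucocorticoid-induced genes were chosen only after their values were seen. Border macrophages, the macrophages of meninges and vessels, held far less MHC class II RNA in the 60TM library: the list had 0 of 4 members higher and 4 lower, with a median log2 ratio of −3.85 (−4.34 to −3.38). H2-Aa stood at 227 CPM in WT and 16.4 CPM in 60TM, 13.8-fold lower, H2-Ab1 was 35.8-fold lower, and H2-Eb1 had 99 UMIs in WT and 2 in 60TM, 78.7-fold lower (21.2 to 659). Cd74, the chain that guides MHC class II, was 2.84-fold lower. Homeostatic microglia genes, which mark another cell type, were lower in the same class, 9 of 12 with a median of −1.0 (−1.23 to −0.79), so the class of 81 WT and 121 60TM cells differed in more than MHC class II. Lyve1, a receptor for hyaluronan on vessel-associated macrophages, was higher, at 717 and 1591 CPM (ratio 2.22), while the macrophage markers Mrc1 and Cd163 had ratios of 0.973 and 1.04. Interferon response genes were higher in this class too, with 14 of 18 members and a median of 1.46, and MHC class I genes had 0.72. Choroid plexus cells had higher immediate early genes (9 of 12, median 0.97) and calcium handling genes (8 of 10, median 0.59), and lower myelin genes (9 of 9, median −1.43), which are RNA of another cell type. Free RNA by the markers of other classes made up 6.45% of UMIs in WT and 2.59% in 60TM choroid plexus cells.

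Cell cycle genes of microglia were higher in 60TM on few UMIs. Mki67, present in dividing cells, had 2 UMIs in WT and 35 in 60TM, a ratio of 12.4 (3.18 to 106), Top2a a ratio of 3.11 and Mcm2 of 2.80. Because Sgk1, Fkbp5, Zbtb16 and Plin4 of the oligodendrocytes respond to glucocorticoids, 11 other genes of that response were listed. The median log2 ratio of those with enough UMIs was 0.32 in oligodendrocytes and 0.51 in microglia (10 genes each), 0.21 in endothelial cells and 0.05 in OPCs (8 each), and 0.13 in astrocytes (11).

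Few genes differed alike in many classes. Of 4733 genes with at least 40 UMIs in each of 6 classes (astrocytes, microglia, oligodendrocytes, OPCs, endothelial cells and immature neurons), 2 were at least 2-fold higher in all of them and 0 lower. Ttr, the transthyretin of the choroid plexus, had ratios of 17.1 in astrocytes, 10.5 in microglia, 9.68 in oligodendrocytes, 14.1 in OPCs, 10.9 in endothelial cells and 15 in immature neurons, but 1.03 in choroid plexus cells, where it was at 258058 and 266175 CPM. Choroid plexus cells were 0.986% of the WT and 3.21% of the 60TM library. Hnrnpa0 had ratios of 2.17, 2.24, 2.28, 2.30, 2.39 and 2.32 in the same 6 classes. Haemoglobin genes were at 168 CPM over all kept cells in WT and 1.69 CPM in 60TM. Both libraries held cells with Y-linked UMIs, 72.0% in WT and 68.0% in 60TM, and Xist was present in 11 and 14 cells. For each 100 UMIs of astrocyte markers, Gfap had 1.85 UMIs in WT and 7.58 in 60TM astrocytes, 1.69 and 6.10 in microglia, 5.79 and 30.9 in endothelial cells, and 0.208 and 14 in pericytes. Endothelial Lcn2 was at 17.6 CPM in WT and 78.7 CPM in 60TM, a ratio of 4.47.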
